A study of Mus musculus with 8 samples.

How the data were processed

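RNA was measured in 8 libraries of proliferating C2C12 mouse myoblasts, 2 for each of 4 shRNAs (scramble, Brd9, Baf250A and Baf180). Total RNA was extracted with TRIzol, libraries were prepared at BGI, and sequencing was on a BGISEQ-500. The deposited table holds estimated counts per gene and library, which the authors made from the reads and which are not normalised. The submitters' processing notes name HISAT2, StringTie, Cufflinks, Bowtie2, RSEM and DESeq2 and the build mm10, without saying which step each served, and versions are not given in the sources used here. A further column gives, per the file headers, another value, the length of each gene in bases. Whether counting was strand-specific is not given in the sources used here, so counts of genes that overlap on opposite strands are uncertain. No unique molecular identifiers are stated, and counting intervals and floors cover counting error only.

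The table has 24573 genes, of which 24479 were matched to names and coordinates by gene ID and 9 by RefSeq accession, while 85 were not matched and kept their ID. Coordinates come from a RefSeq gene table on GRCm38, the assembly that mm10 also denotes. Groups were taken from the sample titles and the count columns that repeat them. Library totals were 18575484 and 17763062 counts for scramble, 18371432 and 18148388 for Brd9, 19101528 and 18249484 for Baf250A, and 20400855 and 18941101 for Baf180. A count was seen for 18092 genes.

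Estimated counts carry decimals and were rounded to whole numbers. Genes were kept by filterByExpr with its defaults, which left 12420, and libraries were scaled by TMM, with factors from 0.846 (Baf180 replicate 1) to 1.12 (Brd9 replicate 1). All 8 libraries entered a single quasi-likelihood fit in edgeR 4.0.16 (glmQLFit and glmQLFTest, R 4.3.3) with a factor of 4 groups and no further covariate, so that the spread was estimated from all groups together. Each knockdown was compared with scramble and with each other knockdown, 6 comparisons in all. P-values were adjusted by Benjamini-Hochberg within each comparison, and genes at an adjusted p below 0.05 were called. The standard error is the absolute log2 fold change divided by the square root of F. CPM are counts scaled to the TMM-adjusted library size, with the SD of 2 libraries. A gene with 0 counts in both libraries of a group was given a bound from a floor of 3 counts per library, and a gene with 1 to 3 counts there a ratio of counts with an exact 95% interval.

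Named genes followed a rule fixed before the values were seen. They are the targets, the 6 largest rises and 6 largest falls per comparison with scramble among called genes with a mean of at least 5 CPM and both knockdown libraries beyond both scramble libraries (3 and 3 between knockdowns), up to 2 members with the lowest p of each list described, and 8 genes of myogenesis and the cell cycle whatever their result. Unnamed gene models were passed over. The 36 gene lists were also fixed before, and were tested with camera in limma 3.58.1 at a preset correlation between genes of 0.01, adjusted over the lists with 3 or more tested members. List members are given as called over all genes, and as called when adjusted over the list alone. Fractions of a list count only members that passed the filter. These were 6 of 14 adipogenic markers, 10 of 20 neural markers and 25 of 54 muscle structural genes, so they do not describe a whole lineage programme.

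Alternatives planned in advance were RLE and upper-quartile scaling, no filter, a filter on a mean of at least 5 CPM, DESeq2 1.42.0, limma-voom, a fit of the 4 libraries of a comparison alone, the replicate number as a block, each library left out in turn, a test against a fold change of 1.5, an adjusted p below 0.01 for overlaps, and for lists an estimated correlation and fry. An alternative chosen after the data were seen adds GC and length offsets. In each library a loess curve (span 0.3) of the deviation of log2 CPM from the gene's mean was fitted on transcript GC content, then on log2 gene length, and passed to edgeR as an offset. GC content came from GENCODE release M21 transcripts matched by RefSeq accession and was found for 98.95% of tested genes. The offsets also remove any change in expression that itself follows GC content.

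The procedure was tested on simulated counts with the depths and spread of these libraries, 200 genes changed and no trend added. Of changes of 1.5-fold it recovered 12.9% (Brd9), 10% (Baf250A) and 14.3% (Baf180), of 2-fold changes 68.3%, 68.8% and 62.3%, and of 4-fold changes 95.5%, 98.5% and 98.6%, with 9, 8 and 7 false calls. With the GC and length trend added, unchanged genes gave 2, 284 and 91 false calls under TMM and 4, 6 and 10 with the offsets. These were 2.47%, 73.8% and 47.4% of all calls under TMM, and 3.54%, 5.08% and 8.33% with the offsets. The adjusted p of the main fit thus understates false calls for Baf250A and Baf180 where such a trend is present. TMM then recovered 1.43%, 14.3% and 12.9% of 1.5-fold and 26.98%, 42.2% and 44.3% of 2-fold changes. The offsets recovered 61.9%, 56.2% and 57.4% of 2-fold changes. The simulated spread was estimated without the offsets, so it already held replicate differences along GC content before the trend was added. The added trend is of the kind that the offsets remove, so their few false calls were largely set in advance. Overlaps of calls were set beside the number expected for independent lists (n1 × n2 / N) and beside 20 simulations of unchanged groups that share the scramble libraries. Tables and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.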

Results

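Gene expression was measured by RNA sequencing in C2C12 cells, a mouse myoblast line that proliferates as muscle precursors and forms myotubes when serum is withdrawn. The cells were harvested while proliferating, after lentiviral delivery of a short hairpin RNA (shRNA) and selection in puromycin. The shRNA was a scrambled control or was directed against Brd9, Baf250A or Baf180. Each target is a subunit of a different form of the SWI/SNF (BAF) family of ATP-dependent chromatin remodellers: Brd9 of non-canonical BAF (ncBAF), Baf250A, encoded by Arid1a, of canonical BAF (cBAF), and Baf180, encoded by Pbrm1, of PBAF. The comparisons ask which genes depend on each form in growing myoblasts, and whether the forms act on the same genes. The 8 libraries formed 4 groups of 2, and every mean, fold change and error below rests on 2 libraries per group. Totals ran from 17763062 estimated counts (scramble replicate 2) to 20400855 (Baf180 replicate 1). Nothing in the labels says that the 2 libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. The table names 1 shRNA per target, so off-target effects cannot be separated from loss of the target. The design has 1 scramble line, so a change common to the knockdowns cannot be separated from a difference of that line.

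The targeted genes were lower in the libraries labelled with their shRNA. Brd9 (chromosome 13, 73937801 to 73960895, mm10, which is GRCm38) had 157 and 135 counts in the Brd9 libraries and 717 and 637 in the scramble libraries, a 5.24-fold fall (log2 fold change −2.39, SE 0.16, adjusted p = 7.48e-05). It had 768 and 838 counts in the Baf250A libraries and 593 and 670 in the Baf180 libraries. Arid1a (chromosome 4, 133679008 to 133756769) had 1335 and 1243 counts in the Baf250A libraries and 2834 and 2720 in the scramble libraries, a 2.41-fold fall (log2 fold change −1.27, SE 0.12, adjusted p = 0.000184). In the Brd9 libraries it had 3618 and 3215 counts, and in the Baf180 libraries 2747 and 3269. Pbrm1 (chromosome 14, 31019138 to 31121592) had 65 and 86 counts in the Baf180 libraries and 876 and 969 in the scramble libraries, a 12.4-fold fall (log2 fold change −3.63, SE 0.28, adjusted p = 7.04e-05). Its counts were 1365 and 957 in the Brd9 libraries. In the Baf250A libraries Pbrm1 had 1483 and 2325 counts and was called higher (log2 fold change 0.89, SE 0.23, adjusted p = 0.0211). That call ended when either scramble library or Baf250A replicate 2 was left out (adjusted p up to 0.135), and with the GC and length offsets defined below (log2 fold change 0.14, SE 0.09, adjusted p = 0.233).

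**Figure D1:**
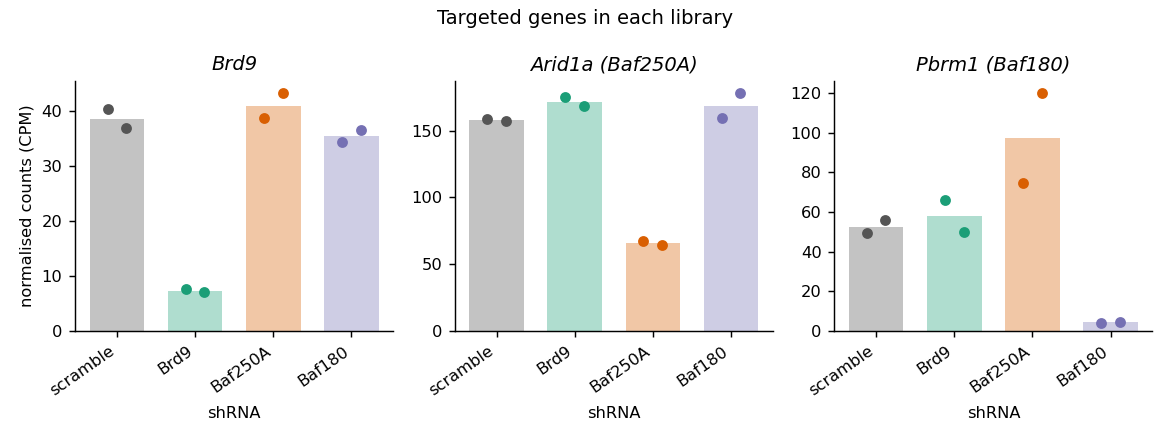
Normalised counts scaled to library size (CPM, vertical axis, from 0) of the 3 targeted genes in each library (points) by shRNA (horizontal axis), with bars at the mean of the 2 libraries. Each target is lowest in the libraries carrying its own shRNA, at a mean of 7.34 CPM for Brd9, 65.7 CPM for Arid1a and 4.23 CPM for Pbrm1.

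The libraries also differed along the GC content of transcripts, within groups as well as between them. Among the 1229 tested genes with the lowest GC content (33.2 to 42.3%), the median deviation from the mean of the libraries was 1.06 on the log2 scale in Baf250A replicate 2 and 0.48 in Baf250A replicate 1. It was −1.10 in Baf180 replicate 1 and −0.69 in Baf180 replicate 2, 0.44 in Brd9 replicate 1 and 0.05 in Brd9 replicate 2, and −0.18 and −0.01 in the scramble libraries. Across genes, which are not independent replicates, the fold changes against scramble followed GC content with a Spearman rho of −0.30 for Brd9, −0.53 for Baf250A and 0.59 for Baf180 knockdown. Each count of genes was therefore computed again with per-library offsets that remove the trend with GC content and gene length, an alternative chosen after the data were seen. Scramble replicate 2 stood apart in another way, with 16402 genes detected against 14195 to 14768 in each other library.

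**Figure D2:**
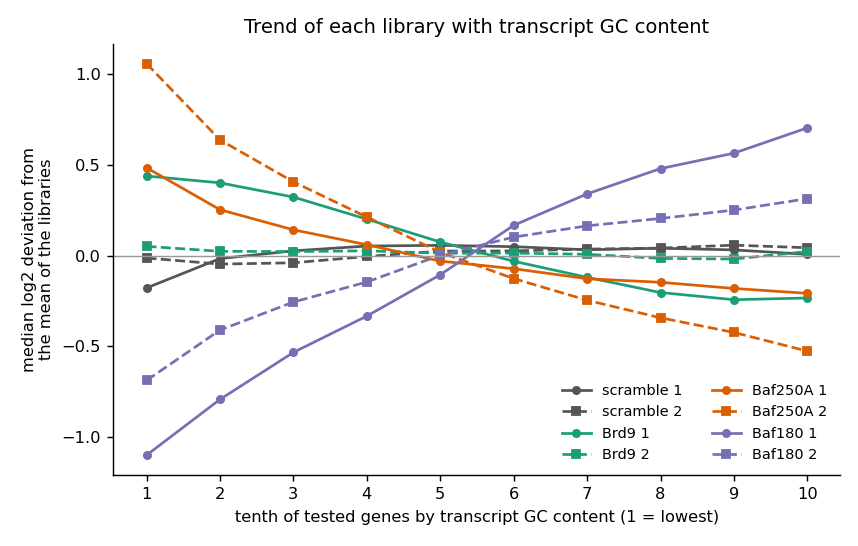
Median log2 deviation of each library from the mean of the libraries (vertical axis) in 10 bins of the tested genes ordered by transcript GC content (horizontal axis, 1 is lowest). Lines are libraries, with colour for the group and line style for the replicate. The Baf250A and Baf180 libraries run in opposite directions, from 1.06 in Baf250A replicate 2 to −1.10 in Baf180 replicate 1 in the lowest bin.

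Against scramble, Brd9 knockdown had extracellular matrix, Notch pathway and myogenic regulator genes higher. Genes of ribosome biogenesis, ribosomal proteins and DNA replication were lower. With an estimated correlation between genes, 0 of the 18 lists called in Brd9 knockdown stayed called. Sfrp2, a secreted modulator of Wnt signalling, rose 33.8-fold (log2 fold change 5.08, SE 0.32, adjusted p = 6.05e-05), from 2.01 ± 0.885 to 68.3 ± 20.7 CPM (SD, n = 2). Slco4a1, an organic anion transporter on chromosome 2 (180456226 to 180474853), fell 47.8-fold (log2 fold change −5.58, SE 0.21, adjusted p = 7.09e-06), from 37.6 ± 1.04 to 0.777 ± 0.136 CPM. Of the 12420 genes tested, 801 were higher and 443 lower at the threshold. Higher genes made up 64.4% of these 1244 calls, 52.7% of the calls of DESeq2 and 51.0% of those with the GC and length offsets, so the excess of higher over lower calls depends on the method. The count was 231 without scramble replicate 2, 358 without scramble replicate 1 and 381 without Brd9 replicate 1, and 3511 with the offsets, which kept 98.4% of the calls in the same direction.

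Other genes with large rises in Brd9 knockdown were Igdcc4, an immunoglobulin superfamily receptor (log2 fold change 4.83, SE 0.28), Prelp, a leucine-rich matrix proteoglycan (4.46, SE 0.31), Lpl, the lipoprotein lipase (4.21, SE 0.37), and Fbln7, a fibulin of the matrix (3.76, SE 0.26). Their adjusted p-values ran from 5.77e-05 (Igdcc4) to 0.000265 (Lpl). Large falls were seen for Crmp1, a neuronal cytoskeleton regulator (−3.83, SE 0.40), Ngfr, the low-affinity neurotrophin receptor (−3.25, SE 0.26), Dok7, an adaptor of neuromuscular synapse formation (−2.78, SE 0.29), and Car8, a carbonic anhydrase family member (−2.65, SE 0.24). Their adjusted p-values ran from 0.000195 (Ngfr) to 0.000669 (Crmp1 and Dok7). For each gene called by name without the offsets, here and in the other comparisons, both libraries of 1 group lay beyond both libraries of the other. Tmem254b had 0 counts in both Brd9 libraries and 232 and 197 in the scramble libraries, which makes it at least 80.7-fold lower at a floor of 3 counts per library. Its neighbour Tmem254c had 266 and 260 counts against 1 and 1, a ratio of 232. These are near-identical copies on chromosome 14, so both values are uncertain. Tmem254b stood at 12.2 CPM in the scramble libraries and Tmem254c at 13.3 CPM in the Brd9 libraries, so counts may have moved between the copies. Neither ratio is taken as a change in expression.

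In Brd9 knockdown 29 of 57 tested extracellular matrix genes rose and 2 fell (36 and 3 adjusted over the list alone), with a median log2 fold change of 0.61 (adjusted p = 1.07e-17 by camera, adjusted p = 0.0753 with an estimated correlation). They included Nid2, a basement membrane nidogen (log2 fold change 2.24, SE 0.13), and Adamts2, a procollagen protease (1.96, SE 0.15). Of 32 myogenic regulators, 16 rose and 1 fell (17 and 1 adjusted over the list alone, median 0.60, adjusted p = 2.43e-06, adjusted p = 0.0753 with an estimated correlation). Among them were Notch3, a receptor expressed in muscle progenitors (2.10, SE 0.17, adjusted p = 0.000199), and Fgfr4, a myoblast growth factor receptor (2.25, SE 0.29, adjusted p = 0.00208). Notch pathway genes showed 6 of 13 higher and 1 lower (6 and 1 adjusted over the list alone, median 0.82, adjusted p = 0.000436, adjusted p = 0.11 with an estimated correlation). Hey1, a Notch effector, rose by 1.63 (SE 0.23, adjusted p = 0.00295, adjusted p = 0.0514 without scramble replicate 2). In the list of muscle structural genes 9 of 25 rose and 3 fell, without a shift of the list (adjusted p = 0.267), though the list was called lower among genes with a mean of at least 5 CPM. There Ldb3, a Z-disc protein, rose (1.78, SE 0.16) and Tnnt2, a troponin, fell (−2.06, SE 0.14).

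Among markers of other cell types, smooth muscle genes rose in Brd9 knockdown, with 5 of 11 higher and none lower (6 and 0 adjusted over the list alone, median 0.47, adjusted p = 4.68e-05, adjusted p = 0.297 with an estimated correlation). Lmod1, an actin nucleator of smooth muscle, rose 6.83-fold and Cnn1, a calponin, 3.39-fold. Adipogenic markers had 3 of 6 higher and none lower (4 and 0 adjusted over the list alone, median 0.66, adjusted p = 1.97e-06, adjusted p = 0.0753 with an estimated correlation), with Lpl and Cebpa, an adipocyte transcription factor (2.07, SE 0.17). Neural markers shifted down, with 3 of 10 lower and 1 higher (3 and 1 adjusted over the list alone, median −0.31, adjusted p = 9.72e-06, adjusted p = 0.0753 with an estimated correlation). The neurofilament genes Nefl (−2.36, SE 0.15) and Nefm (−2.06, SE 0.17) were the members with the lowest p.

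Growth-related genes moved down in Brd9 knockdown by small amounts. Housekeeping genes also moved down, with a median log2 fold change of −0.36, 2 of 16 lower and none higher. The growth-related lists were not tested against housekeeping genes, so a fall particular to growth was not shown. Of 29 genes of ribosome biogenesis, 14 fell and none rose (22 and 0 adjusted over the list alone, median −0.62, adjusted p = 1.95e-10, adjusted p = 0.152 with an estimated correlation), among them the nucleolar proteins Nop56 (−0.71, SE 0.12) and Nhp2 (−0.87, SE 0.18). Of 76 ribosomal protein genes 12 fell and none rose (40 and 0 adjusted over the list alone, median −0.46, adjusted p = 6.25e-14, adjusted p = 0.297 with an estimated correlation), such as Rpsa (−0.75, SE 0.15) and Rpl7a (−0.62, SE 0.13). Of 50 DNA replication genes 12 fell and none rose (24 and 0 adjusted over the list alone, median −0.42, adjusted p = 1.98e-08, adjusted p = 0.152 with an estimated correlation), including E2f2 (−1.26, SE 0.15) and the licensing factor Cdt1 (−0.77, SE 0.16). Mitotic genes were also called as a list, with 3 of 50 lower and none higher (0 and 0 adjusted over the list alone, median −0.21, adjusted p = 0.00295, adjusted p = 0.297 with an estimated correlation). Their median transcript GC content was low, at 46.9%, and with the offsets 26 were lower and 2 higher (median −0.30), against 27 and 0 of the DNA replication genes (median −0.36). Of these genes Nop56, Nhp2, Rpsa, Rpl7a and Cdt1 were no longer called when scramble replicate 1, scramble replicate 2 or Brd9 replicate 1 was left out (adjusted p up to 0.175), while E2f2 was called in each such fit.

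In Brd9 knockdown 8 more lists were called. Oxidative phosphorylation genes were lower (2 of 46 lower, none higher, adjusted p = 0.000385, adjusted p = 0.43 with an estimated correlation, median −0.30 and with the offsets −0.18), as were housekeeping genes (2 of 16 lower, none higher, adjusted p = 0.00245, adjusted p = 0.23 with an estimated correlation). Immediate early genes were lower (6 of 24 lower, 1 higher, adjusted p = 0.0138, adjusted p = 0.152 with an estimated correlation), a call that ended with the offsets (adjusted p = 0.129, median −0.32 before and −0.17 after). Targets of transforming growth factor beta and BMP signalling were higher (9 of 28, none lower, adjusted p = 0.00445, adjusted p = 0.23 with an estimated correlation). Wnt targets were higher (4 of 14, 2 lower, adjusted p = 0.00295, adjusted p = 0.23 with an estimated correlation), and p53 targets too (5 of 27, none lower, adjusted p = 0.0148, adjusted p = 0.152 with an estimated correlation). CDK inhibitor and senescence genes were higher (5 of 18, none lower, adjusted p = 0.0163, adjusted p = 0.43 with an estimated correlation), with a call that ended without scramble replicate 2 (adjusted p = 0.0802). Interferon-stimulated genes were higher (4 of 37, none lower, adjusted p = 0.0278, adjusted p = 0.164 with an estimated correlation), with a call that ended without scramble replicate 1 (adjusted p = 0.0749). Adjusted over the list alone, these lists had 0 higher and 2 lower members, 0 and 5, 3 and 9, 10 and 0, 6 and 3, 9 and 2, 7 and 1, and 8 and 1, in the same order.

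Against scramble, Baf250A knockdown had neural, muscle structural and cholesterol synthesis genes lower and smooth muscle, inflammatory and matrix genes higher. With an estimated correlation 1 of its 14 called lists, that of neural markers, stayed called. Col2a1, the type II collagen of cartilage (chromosome 15, 97975602 to 98004724), rose 98.4-fold (log2 fold change 6.62, SE 0.37, adjusted p = 1.31e-05), from 0.315 ± 0.208 to 31.5 ± 4.57 CPM (SD, n = 2). With 1 library left out its log2 fold change ranged from 6.07 to 7.49. Chrna1, the muscle acetylcholine receptor alpha subunit, fell 18.9-fold (log2 fold change −4.24, SE 0.15, adjusted p = 1.37e-06), from 302 ± 0.0728 to 15.9 ± 0.207 CPM. Of 12420 genes, 1926 were higher and 1743 lower, 3669 in all, against 2117 and 1595 with RLE and 1867 and 1919 with upper-quartile scaling. The count was 1171 without scramble replicate 1, 1524 without scramble replicate 2 and 1281 without Baf250A replicate 2. With the GC and length offsets 4417 genes were called, and 74.1% of the 3669 calls stood in the same direction, while 131 had the other sign.

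Further large rises in Baf250A knockdown were those of Coch, a secreted protein of the inner ear matrix (log2 fold change 5.84, SE 0.42), Lama4, a laminin alpha chain (4.92, SE 0.26), Il1rn, the interleukin-1 receptor antagonist (4.83, SE 0.34), Ptgfr, the prostaglandin F receptor (4.34, SE 0.36), and Pi15, a peptidase inhibitor (4.31, SE 0.53). Their adjusted p-values ran from 1.11e-05 (Lama4) to 0.000684 (Pi15), and with the offsets Ptgfr stood at 3.46 and Pi15 at 2.79. Pi15 ranged from 3.57 to 5.87 with 1 library left out. The largest falls were in genes with almost no counts left. Stmn4, a neuronal tubulin regulator, had 0 and 2 counts against 837 and 685, a ratio of 0.00118 (95% counting interval 0.000142 to 0.00425). St8sia2, the sialyltransferase that adds polysialic acid to NCAM, had 1 and 0 counts against 272 and 184, a ratio of 0.00196 (95% counting interval 4.96e-05 to 0.011). Ngfr (−5.79, SE 0.32), Xirp1, an actin-binding protein of striated muscle (−5.22, SE 0.28), Rnf144b, a ubiquitin ligase (−5.18, SE 0.32), and Dok7 (−4.92, SE 0.35) also fell, with adjusted p-values from 1.22e-05 (Xirp1) to 4.08e-05 (Dok7). Counting intervals and floors cover counting error only.

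Of 10 tested neural markers 8 fell and none rose in Baf250A knockdown (8 and 0 adjusted over the list alone, median log2 fold change −3.24, adjusted p = 4.45e-28). This was the list call that held with an estimated correlation (adjusted p = 0.0133). Nefl fell from 260 ± 18.9 to 11.6 ± 0.179 CPM (log2 fold change −4.48, SE 0.17) and Stmn2, a neuronal stathmin, by 2.83 on the log2 scale (SE 0.15). Of 25 muscle structural genes 12 fell and 3 rose (12 and 3 adjusted over the list alone, median −0.57, adjusted p = 1.04e-05, adjusted p = 0.255 with an estimated correlation), Chrna1 and Xirp1 among the falls. Myogenic regulators were divided, with 8 of 32 higher and 5 lower and no shift of the list (adjusted p = 0.834, median 0.02 and mean −0.34, so that the sign is not defined). Within that list Cdh15, the M-cadherin of myoblasts, fell 5.50-fold (−2.46, SE 0.20, adjusted p = 8.29e-05). Msc, a repressor of myogenic transcription, had 0 counts in both Baf250A libraries against 87 and 94, at least 33.7-fold lower at the floor of 3 counts per library.

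Cholesterol synthesis genes fell in Baf250A knockdown, with 16 of 25 lower and none higher (16 and 0 adjusted over the list alone, median −0.75, adjusted p = 1.8e-06, adjusted p = 0.138 with an estimated correlation). Lss, lanosterol synthase, and Nsdhl, a sterol dehydrogenase, each fell by 1.29 (SE 0.13 and 0.13, adjusted p = 0.00023 and 0.000233). Genes of the unfolded protein and Atf4 response were lower, with 10 of 29 lower and 2 higher (12 and 2 adjusted over the list alone, median −0.29, adjusted p = 0.0158, adjusted p = 0.444 with an estimated correlation). That call ended with the offsets (median −0.17, adjusted p = 0.0815), though Chac1, a glutathione-degrading Atf4 target, fell by 2.00 before (SE 0.18) and by 1.59 after.

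Among the lists that shifted up in Baf250A knockdown, inflammatory NF-kB targets had 11 of 19 higher and 1 lower (13 and 2 adjusted over the list alone, median 1.06, adjusted p = 3.01e-08, adjusted p = 0.138 with an estimated correlation). The chemokine genes Ccl7 (2.12, SE 0.15) and Cxcl1 (1.85, SE 0.13) rose to 138 ± 17.4 and 170 ± 11.1 CPM. Smooth muscle markers had 8 of 11 higher and 1 lower (8 and 1 adjusted over the list alone, median 1.55, adjusted p = 1.58e-06, adjusted p = 0.279 with an estimated correlation), with Cnn1 higher (2.38, SE 0.15) and Cspg4, a pericyte proteoglycan, lower (−2.49, SE 0.15). Extracellular matrix genes had 29 of 57 higher and 7 lower (30 and 9 adjusted over the list alone, median 0.52, adjusted p = 1.28e-05, adjusted p = 0.242 with an estimated correlation), with Lama4 and Adamts2 (2.59, SE 0.15). Targets of transforming growth factor beta and BMP had 17 of 28 higher and 1 lower (17 and 1 adjusted over the list alone, median 0.74, adjusted p = 1.28e-05, adjusted p = 0.138 with an estimated correlation), with Bmp4 itself 8.05-fold higher (SE 0.23 on the log2 scale) and the inhibitory Smad6 2.89-fold higher (SE 0.15). Adipogenic markers had 4 of 6 higher and 1 lower (4 and 1 adjusted over the list alone, median 1.31, adjusted p = 0.000244, adjusted p = 0.138 with an estimated correlation), with Cebpd (2.04, SE 0.16) and Cebpa (1.79, SE 0.17). Wnt targets had 8 of 14 higher and 1 lower (8 and 2 adjusted over the list alone, median 1.11, adjusted p = 0.000381, adjusted p = 0.242 with an estimated correlation), led by the Wnt modulators Sfrp2 (3.83, SE 0.31) and Sfrp1 (3.21, SE 0.48).

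The other 4 lists called in Baf250A knockdown each lost the call when 1 library was left out. CDK inhibitor and senescence genes were higher (9 of 18, 2 lower, 10 and 2 adjusted over the list alone, adjusted p = 0.0125, adjusted p = 0.436 with an estimated correlation, median 0.62 and with the offsets 0.28), and not called without scramble replicate 2 (adjusted p = 0.0657). The rises included the secreted chemokines Cxcl5 (2.88, SE 0.25, 1.79 with the offsets) and Cxcl1. Mitotic genes were higher (21 of 50, 2 lower, 21 and 3 adjusted over the list alone, adjusted p = 0.0361, adjusted p = 0.444 with an estimated correlation), and not called without scramble replicate 2 (adjusted p = 0.0657) or with the offsets (adjusted p = 0.402, median 0.19 before and 0.02 after). Smc2, a condensin subunit in that list, rose by 1.74 (SE 0.29), with CPM of 126 ± 60.1, and stood at 0.63 with the offsets. Osteogenic and chondrogenic markers were higher (5 of 13, 2 lower, 7 and 2 adjusted over the list alone, adjusted p = 0.0316, adjusted p = 0.242 with an estimated correlation, median 0.53 and with the offsets 0.35), among them Col2a1 and Spp1, osteopontin (2.12, SE 0.22). YAP and TEAD targets were higher (10 of 24, 2 lower, 11 and 2 adjusted over the list alone, adjusted p = 0.0361, adjusted p = 0.376 with an estimated correlation), Crim1 by 1.64 (SE 0.18), while Wwc1, an upstream Hippo regulator in the list, fell (−2.46, SE 0.22). The osteogenic list and the YAP list were not called without scramble replicate 2 or without Baf250A replicate 1 (adjusted p up to 0.0561 and 0.107).

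Against scramble, Baf180 knockdown had extracellular matrix, smooth muscle and cholesterol synthesis genes higher and neural, mitotic and ribosome biogenesis genes lower. None of these calls held with an estimated correlation, where 0 of 13 lists stayed called. The matrix, smooth muscle and neural lists were called in the same direction in each knockdown, so a difference of the scramble line could also give those shifts. Svep1, a large matrix adhesion protein (chromosome 4, 58042796 to 58206596), rose 19.2-fold (log2 fold change 4.26, SE 0.16, adjusted p = 1.74e-06), from 10.8 ± 1.79 to 207 ± 6.13 CPM (SD, n = 2). Nefl (chromosome 14, 68083863 to 68089095) fell 130-fold (log2 fold change −7.02, SE 0.20, adjusted p = 4.72e-07), from 260 ± 18.9 to 1.98 ± 0.511 CPM. Of 12420 genes 2142 were higher and 2111 lower, 4253 in all, and 1857 and 2537 with upper-quartile scaling, so the balance depends on the scaling. The count was 1560 without scramble replicate 2, 1755 without scramble replicate 1 and 1680 without Baf180 replicate 1. With the GC and length offsets 4745 genes were called, and 70.1% of the 4253 calls stood in the same direction, while 99 had the other sign.

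Large rises in Baf180 knockdown were also seen for Aoc3, an amine oxidase of smooth muscle and adipocytes (log2 fold change 4.87, SE 0.27), Sfrp2 (4.60, SE 0.31), Lama4 (4.53, SE 0.26), Fndc1, a fibronectin domain protein (4.36, SE 0.15), and Prelp (4.17, SE 0.31). Their adjusted p-values ran from 1.56e-06 (Fndc1) to 5.74e-05 (Prelp). Among the falls, Stmn4 had 4 and 4 counts (−7.55, SE 0.36), Gap43, a growth cone protein, had 7 and 12 (−6.10, SE 0.30), and Ngfr had 8 and 9 (−5.95, SE 0.33). Lrrn1, a neuronal leucine-rich repeat protein, fell by 5.14 (SE 0.37). Their adjusted p-values ran from 7.66e-06 (Stmn4) to 4.85e-05 (Lrrn1). Grk4, a receptor kinase, was called lower (−4.84, SE 1.32, adjusted p = 0.0222), but rests on scramble replicate 2, with 1346 counts against 30 in scramble replicate 1 and 25 and 24 in the Baf180 libraries (adjusted p = 0.72 without that library).

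In Baf180 knockdown 38 of 57 extracellular matrix genes rose and 2 fell (38 and 3 adjusted over the list alone, median 1.09, adjusted p = 1.71e-24, adjusted p = 0.0595 with an estimated correlation), among them Adamts2 (2.91, SE 0.15) and the elastic fibre protein Fbln5 (2.77, SE 0.15). Smooth muscle markers had 10 of 11 higher and none lower (10 and 0 adjusted over the list alone, median 1.27, adjusted p = 5.13e-11, adjusted p = 0.172 with an estimated correlation). Lmod1 rose 9.41-fold and Actg2, the smooth muscle gamma actin, 4.65-fold, to 1232 ± 245 CPM. Adipogenic markers had 5 of 6 higher and none lower (5 and 0 adjusted over the list alone, median 1.56, adjusted p = 4.28e-06, adjusted p = 0.105 with an estimated correlation), with Cebpa (2.68, SE 0.17) and Cebpd (1.70, SE 0.16). Neural markers had 5 of 10 lower and 1 higher (6 and 1 adjusted over the list alone, median −0.86, adjusted p = 3.35e-17, adjusted p = 0.0595 with an estimated correlation), with Nefl and Nefm (−4.70, SE 0.20) the strongest. Myogenic regulators had 14 of 32 higher and 4 lower (15 and 4 adjusted over the list alone, median 0.41, adjusted p = 0.00057, adjusted p = 0.109 with an estimated correlation), with Notch3 (2.02, SE 0.17) and Sox8, a SoxE factor of satellite cells (2.76, SE 0.23). Notch pathway genes had 6 of 13 higher and 1 lower (6 and 1 adjusted over the list alone, median 0.51, adjusted p = 0.00122, adjusted p = 0.138 with an estimated correlation), with Notch3 and the glycosyltransferase Lfng (1.74, SE 0.15). With the offsets the Notch median was 0.23 (adjusted p = 0.0244). Muscle structural genes went both ways, 9 of 25 higher and 6 lower (10 and 6 adjusted over the list alone), without a shift (adjusted p = 0.367). Acta1, the skeletal muscle actin, rose 6.25-fold and Xirp1 fell 19.0-fold.

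Proliferation genes were lower in Baf180 knockdown. Housekeeping genes had a median log2 fold change of −0.26 there, with 4 of 16 lower and 1 higher. They were not called as a list (adjusted p = 0.233 by camera). Of 50 mitotic genes 27 fell and none rose (33 and 0 adjusted over the list alone, median −0.59, adjusted p = 6.57e-07, adjusted p = 0.172 with an estimated correlation), such as Ncapg, a condensin subunit (−1.71, SE 0.25), and Kif23, a cytokinesis kinesin (−1.09, SE 0.16). This list is low in GC content, as are the genes lowest in these libraries, and with the offsets 25 members were lower and 2 higher (median −0.33, adjusted p = 0.000198), Ncapg at −0.91 and Kif23 at −0.74. Of 50 DNA replication genes 18 fell and none rose (18 and 0 adjusted over the list alone, median −0.22, adjusted p = 0.0016, adjusted p = 0.388 with an estimated correlation), among them Orc1 (−1.03, SE 0.17). Of 29 ribosome biogenesis genes 12 fell and none rose (12 and 0 adjusted over the list alone, median −0.33, adjusted p = 4.65e-05, adjusted p = 0.297 with an estimated correlation), with the RNA helicase Ddx21 (−1.13, SE 0.14) and Nop56 (−0.96, SE 0.12), and with the offsets the median was −0.61.

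Cholesterol synthesis genes rose in Baf180 knockdown, with 15 of 25 higher and none lower (15 and 0 adjusted over the list alone, median 0.56, adjusted p = 0.000499, adjusted p = 0.171 with an estimated correlation). Mvk, mevalonate kinase, rose 2.21-fold. Targets of transforming growth factor beta and BMP had 12 of 28 higher and 2 lower (13 and 2 adjusted over the list alone, median 0.51, adjusted p = 8.56e-05, adjusted p = 0.16 with an estimated correlation), with Tgfb3 (1.90, SE 0.13) and Ltbp2, a latent TGF-beta binding family member (1.54, SE 0.15), and with the offsets the median was 0.28. Inflammatory NF-kB targets had 9 of 19 higher and 3 lower (9 and 3 adjusted over the list alone, median 0.54, adjusted p = 0.0102, adjusted p = 0.365 with an estimated correlation), with complement C3 6.88-fold higher, and the list was not called without Baf180 replicate 2 (adjusted p = 0.0772). The list of PBAF subunits was lower (3 of 4, 3 adjusted over the list alone, adjusted p = 0.00316, adjusted p = 0.365 with an estimated correlation, median −0.58 and with the offsets −0.37). It contains the target Pbrm1, and Phf10 in it fell by 0.58 (SE 0.17, adjusted p = 0.0283), a call lost without scramble replicate 1, scramble replicate 2 or Baf180 replicate 1 (adjusted p up to 0.159). With the offsets 4 more lists were called: ribosomal proteins lower (adjusted p = 0.00265), and interferon-stimulated genes (adjusted p = 0.00939), fibroblast and tendon markers (adjusted p = 0.0398) and CDK inhibitor and senescence genes (adjusted p = 0.0364) higher. With an estimated correlation as well, none of the 4 was called (adjusted p = 0.44, 0.151, 0.372 and 0.563 in that order).

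**Figure D3:**
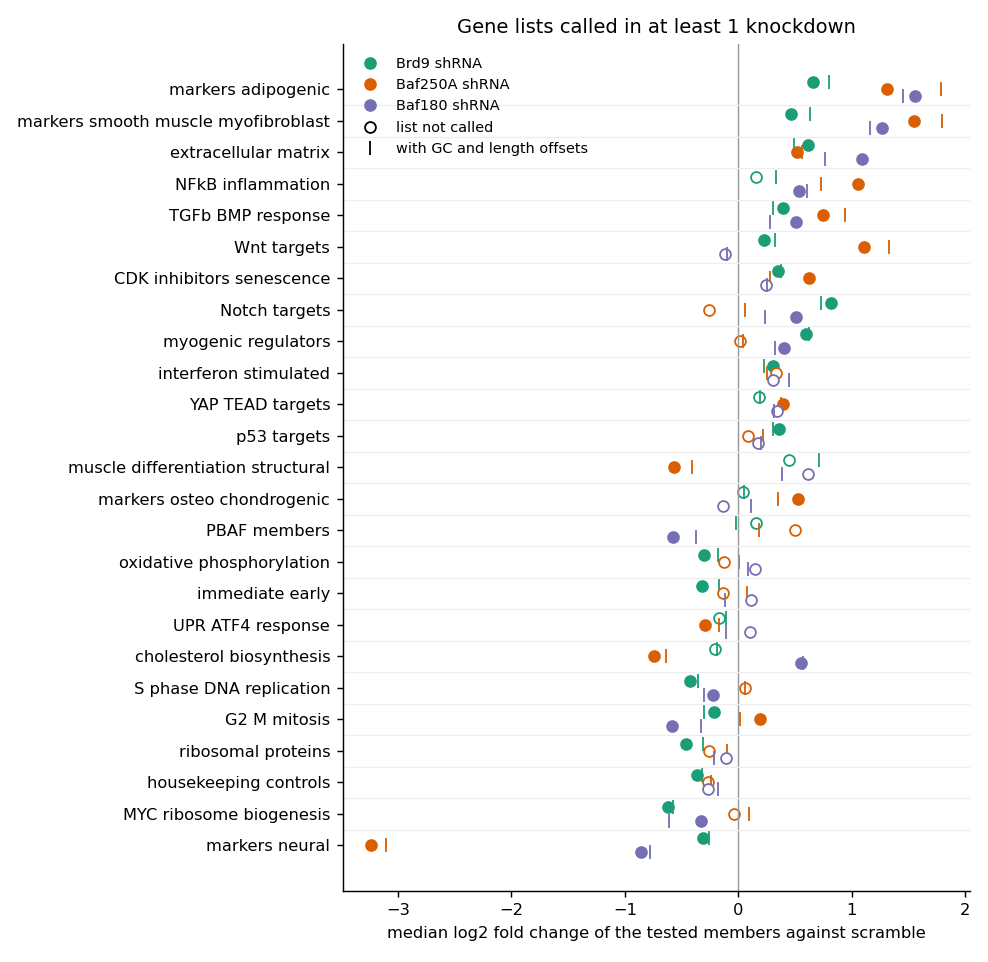
Median log2 fold change against scramble (horizontal axis) of the tested members of each gene list called in at least 1 knockdown (vertical axis). Filled circles are called lists, open circles lists that were not called, and ticks the medians with the GC and length offsets. Neural markers lie at −3.24 in Baf250A knockdown, and cholesterol synthesis genes at −0.75 in Baf250A and 0.56 in Baf180 knockdown.

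Genes that specify and drive the myoblast state were compared with scramble in each knockdown. Pax7, a transcription factor of muscle stem cells (chromosome 4, 139737059 to 139833530), stood at 2.99 ± 0.302 CPM in scramble cells (SD, n = 2). It rose to 10.9 ± 1.01 CPM in Brd9 knockdown (log2 fold change 1.87, SE 0.34, adjusted p = 0.0101) and to 14.6 ± 1.10 CPM in Baf180 knockdown (2.29, SE 0.34, adjusted p = 0.00182). In Baf250A knockdown it fell to 0.556 ± 0.494 CPM (−2.40, SE 0.44, adjusted p = 0.00528), with 18 and 4 counts. The direct test of Baf250A against Baf180 knockdown gave −4.69 for Pax7 (SE 0.41, adjusted p = 6.52e-05). With 1 library left out the fall in Baf250A knockdown ranged from −3.75 to −1.66, and the direct test from −6.06 to −3.97, called in each fit. The Brd9 call was lost without scramble replicate 1, scramble replicate 2 or Brd9 replicate 1 (adjusted p up to 0.103). Myod1, the myogenic determination factor, rose in Baf180 knockdown, from 155 ± 2.31 to 329 ± 52.4 CPM (1.09, SE 0.18, adjusted p = 0.00295). It stood at 0.06 in Brd9 knockdown (SE 0.18, adjusted p = 0.838) and −0.43 in Baf250A knockdown (SE 0.18, adjusted p = 0.0925). With the offsets Myod1 was called higher in Brd9 knockdown too (0.27, adjusted p = 0.0294), and stood at 0.62 in Baf180 and 0.00 in Baf250A knockdown (adjusted p = 0.00023 and 0.989). Myf5, the related factor, fell in Baf180 knockdown (−1.49, SE 0.26, adjusted p = 0.00384) and was called lower in Baf250A knockdown (−0.86, SE 0.25, adjusted p = 0.0331). The Baf250A call was lost without either scramble or either Baf250A library (adjusted p up to 0.183), and in Brd9 knockdown Myf5 stood at −0.24 (SE 0.25, adjusted p = 0.543). With the offsets Myf5 was called lower in each, at −0.50 in Brd9 (adjusted p = 0.0162), −1.53 in Baf250A (adjusted p = 1.71e-05) and −0.82 in Baf180 knockdown (adjusted p = 0.0012).

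Myog, which opens terminal differentiation, was near the detection limit in scramble cells, at 4 and 4 counts. It had 17 and 29 counts in Brd9 knockdown (log2 fold change 2.32, SE 0.59, adjusted p = 0.0395), 28 and 25 in Baf180 knockdown (2.68, SE 0.58, adjusted p = 0.00893) and 2 and 7 in Baf250A knockdown (0.01, SE 0.76, adjusted p = 0.992). The Brd9 call was lost without any scramble, Brd9 or Baf180 library (adjusted p up to 0.203), and the Baf180 call without either scramble library or Baf180 replicate 1 (adjusted p up to 0.0573). Mef2c had at most 8 counts in a library and Pax3 at most 3, so neither was tested, and differences in them were not detectable at this depth. Ccnd1, the G1 cyclin D1, fell in Brd9 knockdown (−0.66, SE 0.13, adjusted p = 0.015) and in Baf180 knockdown (−0.77, SE 0.13, adjusted p = 0.0032), and stood at −0.17 in Baf250A knockdown (SE 0.13, adjusted p = 0.328). Its Brd9 call was lost without scramble replicate 1, scramble replicate 2 or Brd9 replicate 1 (adjusted p up to 0.136). Cdkn1a, the CDK inhibitor p21, rose in Baf180 knockdown (0.91, SE 0.14, adjusted p = 0.00256). It stood at 0.41 in Brd9 knockdown (SE 0.14, adjusted p = 0.0947) and −0.10 in Baf250A knockdown (SE 0.14, adjusted p = 0.619). With the offsets Cdkn1a was called higher in each, at 0.62 in Baf180 (adjusted p = 0.00021), 0.59 in Brd9 (adjusted p = 0.000513) and 0.22 in Baf250A knockdown (adjusted p = 0.0486).

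**Figure D4:**
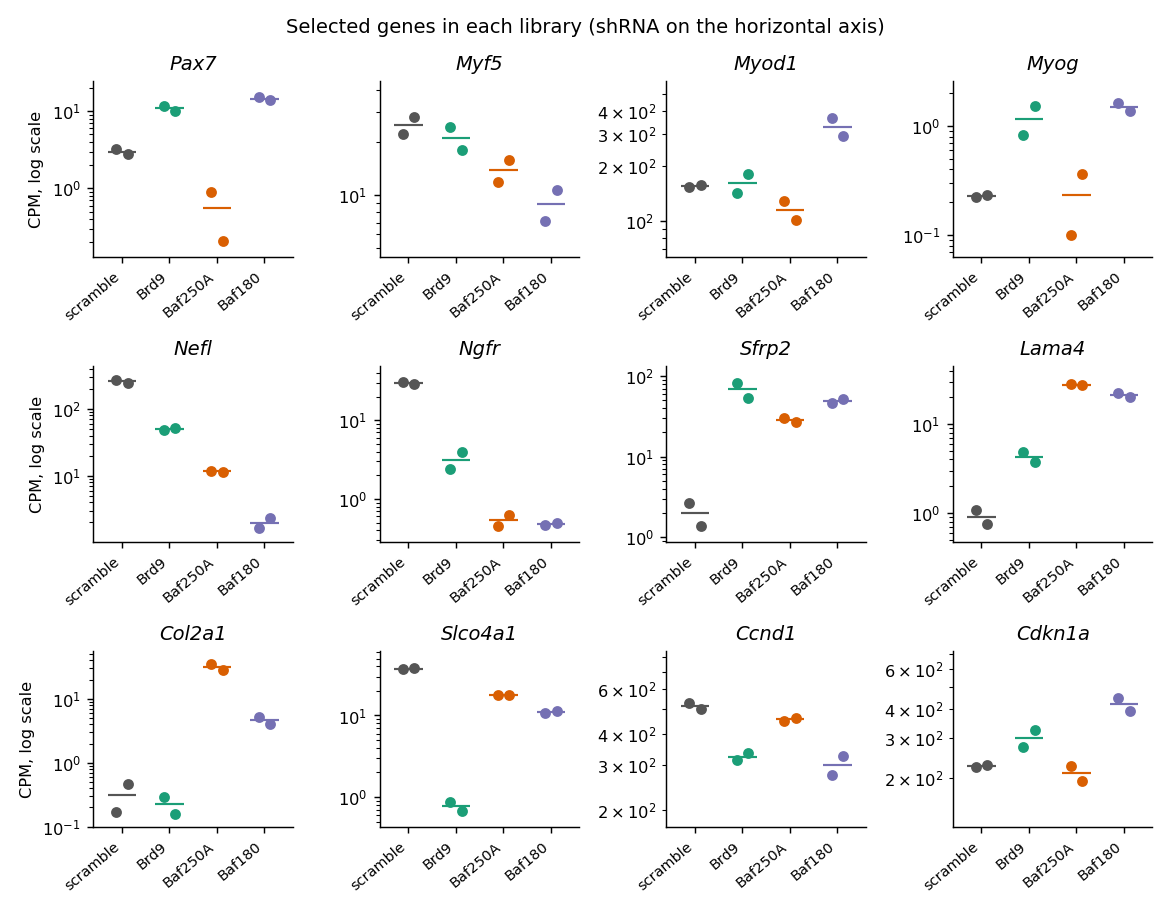
CPM on a log axis (vertical) of 12 genes in each library (points) by shRNA (horizontal axis), with lines at the mean of the 2 libraries. Pax7 lies above scramble in the Brd9 and Baf180 libraries (means of 10.9 and 14.6 CPM against 2.99) and below it in the Baf250A libraries (0.556), and Nefl is below scramble in all 6 knockdown libraries.

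Direct tests between the knockdowns separated them further, gene by gene. Differences of whole lists between knockdowns were not tested. Against Brd9 knockdown, Baf250A knockdown had 1246 genes higher and 1862 lower. The numbers were 1526 and 1682 with RLE scaling, 1650 and 1654 with DESeq2 and 2612 and 2686 with the offsets, so the excess of lower calls depends on the method. Col2a1 was 135-fold higher (log2 fold change 7.08, SE 0.38, adjusted p = 1.79e-05), Coch 23.2-fold (4.54, SE 0.36, 4.03 to 5.38 with 1 library left out) and Slco4a1 22.7-fold (4.50, SE 0.21), while Lrrn1 was 27.1-fold lower (−4.76, SE 0.34). St8sia2, with 1 and 0 counts against 260 and 235, had a ratio of 0.00204, and Stmn4, with 0 and 2 against 261 and 213, of 0.00427. With 1 library left out the log2 fold change ranged from −10.9 to −7.74 for St8sia2 and from −10.8 to −6.72 for Stmn4. The count of 3108 fell to 1381 without Baf250A replicate 2 and 1494 without Brd9 replicate 2, and rose to 5298 with the offsets. Against Baf180 knockdown, Baf250A knockdown had 3824 genes higher and 3942 lower, and 3944 and 3679 with upper-quartile scaling. Coch was 57.8-fold higher and Serpinb2, a plasminogen activator inhibitor, 24.3-fold (4.60, SE 0.37, 2.87 with the offsets). Tspan11, a tetraspanin, was 31.6-fold lower (−4.98, SE 0.39, −5.74 to −4.43 with 1 library left out), Pax7 25.9-fold lower and Enho, a secreted metabolic peptide, lower by a log2 fold change of −4.64 (SE 0.27, −3.55 with the offsets). These libraries are the ends of the GC trend, and 55.1% of the 7766 calls stood with the offsets, while 1586 had the other sign.

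Against Baf180 knockdown, Brd9 knockdown had 3270 genes higher and 2888 lower. With upper-quartile scaling the numbers were 3655 and 2149, and with the offsets 1957 and 2040, so the excess of higher calls depends on the method. Stmn4 (log2 fold change 5.69, SE 0.37) and Lrrn1 (5.32, SE 0.37) were higher, with adjusted p = 0.000123 and 0.000133. Slco4a1 (−3.83, SE 0.21) and Pdgfb, a growth factor subunit (−3.36, SE 0.25), were lower, with adjusted p = 7.3e-05 and 0.00021. Tmem254c was higher and Tmem254b lower, with the uncertainty given above. The count of 6158 fell to 1150 without Brd9 replicate 1 and to 1472 without Baf180 replicate 1. With the offsets it was 3997, 38.96% of the calls stood in the same direction, and 1066 had the other sign.

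Calls against scramble overlapped between the knockdowns. Genes called in the same direction in all 3 numbered 300, of which 213 were higher and 87 lower, where independent lists of these sizes would share 21.4 and 10.6. Sfrp2, Adamts2, Cebpa and Pdgfra were higher in each, and Nefl, Ngfr and Wwc1 lower. The call of Pdgfra in Brd9 knockdown was lost without scramble replicate 2 (adjusted p = 0.0590). Brd9 and Baf180 knockdown shared 503 higher and 169 lower genes (138 and 75.3 for independent lists), with 22 called in opposite directions (213 for independent lists). Brd9 and Baf250A knockdown shared 321 higher and 166 lower genes (124 and 62.2 for independent lists), with 102 in opposite directions (181 for independent lists). Without scramble replicate 2 the former pair shared 125 and 27 (11.4 and 3.32 for independent lists) and the latter 84 and 30 (10.5 and 3.46). Baf250A and Baf180 knockdown shared 359 higher and 278 lower genes (332 and 296 for independent lists), and 1016 genes were called in opposite directions (628 for independent lists). With the offsets the opposite calls of that pair numbered 848 (844 for independent lists) and the shared ones 711 and 543 (424 and 420). Without scramble replicate 1 there were 93 opposite calls (80.8 for independent lists) and 157 and 155 shared ones (33.1 and 47.4), and with another library left out 113 to 1324 opposite calls, so the size of that excess depends on single libraries. All 3 comparisons use the same 2 scramble libraries, which are too few to divide between the comparisons, so part of the excess may come from the shared controls. Unchanged groups simulated against these libraries had at most 0 shared calls in 20 draws, which does not measure that part. The count of 300 was 86 without scramble replicate 2, 141 without scramble replicate 1 and 166 without Brd9 replicate 1.

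Across genes, the fold changes of Brd9 and Baf250A knockdown correlated with Pearson's r = 0.44 (Spearman's rho 0.46), those of Brd9 and Baf180 with r = 0.43 (rho 0.17), and those of Baf250A and Baf180 with r = 0.10 (rho −0.23), a pair whose sign depends on the measure. For that pair r ranged from 0.06 to 0.27 with 1 library left out and was 0.38 with the offsets (rho 0.10). Simulated unchanged groups that share the scramble libraries gave r = 0.51, 0.51 and 0.50, since their fold changes share the chance values of the scramble libraries. The covariance exceeded the simulated one by 0.24, 0.22 and 0.04. The simulation gave all groups the same spread. Chi-square per degree of freedom between replicates was 8.70 in scramble and 28.9 to 36.1 in the knockdown groups. The SD of the difference between replicates was 0.42 in scramble and 0.39 to 0.44 in the knockdown groups. The simulated r and covariance may thus be too high, and the size of the excess is uncertain. With the offsets the covariances were 0.23, 0.33 and 0.26, for which no simulated value was computed. Genes are not independent replicates, and no p-value is attached to these values.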

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

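The calls of the 3 targets in their own knockdowns held under every setting, while the number of called genes depended on single libraries and on the GC trend. Of the named genes called, 33 of 67 for Brd9, 59 of 76 for Baf250A and 62 of 76 for Baf180 knockdown were called in every fit with 1 library left out, and 0 changed sign. With 1 library left out, Brd9 knockdown had 231 to 1558 called genes (1244 with all libraries), Baf250A 1171 to 4114 (3669) and Baf180 1560 to 4514 (4253). Baf250A against Brd9 had 1381 to 3371 (3108) and Brd9 against Baf180 1150 to 6605 (6158). Calls shared in direction ranged from 114 to 620 for Brd9 and Baf250A (487), 152 to 661 for Brd9 and Baf180 (672), 279 to 610 for Baf250A and Baf180 (637), and 86 to 287 for all 3 (300). A group of 1 library leaves less power by construction. With GC and length offsets, an alternative chosen after the data were seen, there were 3511 calls for Brd9, 5298 for Baf250A against Brd9 and 3997 for Brd9 against Baf180, and 1243, 1974, 1254 and 752 shared calls in the same order as above. Pbrm1 in Brd9 knockdown moved from 0.15 to −0.31 and Cdkn1a in Baf250A knockdown from −0.10 to 0.22, neither called before and both called with the offsets (adjusted p = 0.0283 and 0.0486). Without a filter Brd9 had 2588 calls, and 2540 in a fit of 4 libraries; the cause was not tested. Against a fold change of 1.5, a stricter test by construction, calls numbered 303 for Brd9, 1032 for Baf250A, 1014 for Baf180, 962 for Baf250A against Brd9, 4311 for Baf250A against Baf180 and 1170 for Brd9 against Baf180. At an adjusted p below 0.01 the shared calls were 175, 264, 289 and 131. With an estimated correlation 0 lists were called for Brd9, 1 for Baf250A and 0 for Baf180, and the same numbers, 0, 1 and 0, with the offsets as well, while fry called 23 for Baf250A and 21 for Baf180. The list of muscle structural genes in Brd9 knockdown, not called with all genes, was called lower among genes with a mean of at least 5 CPM (signed −log10 of the adjusted p of −1.371); the cause was not tested.

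With the replicate number as a block, 721 genes were called for Brd9 knockdown and 312 were shared by Brd9 and Baf250A. The block also ended 18 calls of named genes, among them Myog, Smarca2, Bicral and Rpl7a in Brd9 knockdown, and 1 list call, that of YAP and TEAD targets in Baf250A knockdown. The deviations of the replicates correlated between groups from −0.48 to 0.46, so the number does not mark a shift common to all groups, and the libraries were not treated as paired.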

Other observations

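In Brd9 knockdown Smarca2, an ATPase subunit, rose (log2 fold change 0.92, SE 0.22, adjusted p = 0.0341), as did Bicral, an ncBAF scaffold (0.80, SE 0.21, adjusted p = 0.0444), and both calls were lost without scramble replicate 1, scramble replicate 2 or Brd9 replicate 1 (adjusted p up to 0.255, Bicral also without Brd9 replicate 2). In Baf250A knockdown Smarcd3 (−1.18, SE 0.21, adjusted p = 0.00401), Smarcc2 (−0.66, SE 0.13, adjusted p = 0.00606) and Dpf2 (−0.70, SE 0.14, adjusted p = 0.00834) fell, and the calls of Smarcc2 and Dpf2 were lost without scramble replicate 1 or Baf250A replicate 2 (adjusted p up to 0.102). In Baf180 knockdown Smarcc1 fell (−0.64, SE 0.14, adjusted p = 0.00846, adjusted p = 0.0842 without scramble replicate 1). By camera the list of shared subunits was not called in any knockdown (adjusted p = 0.338 for Brd9, 0.264 for Baf250A and 0.917 for Baf180). Nor were cBAF subunits (0.79, 0.0709 and 0.665), ncBAF subunits (0.0503, 0.748 and 0.979) or, outside Baf180 knockdown, PBAF subunits (0.666 and 0.205). The alternative fry called shared and cBAF subunits lower in Baf250A knockdown (adjusted p = 0.0227 and 0.00222). The cBAF list contains the target Arid1a, and 2 of its 4 tested members were called lower (median −0.53, and −0.23 with the offsets). Fry also called ncBAF subunits lower in Brd9 knockdown (adjusted p = 0.00151). With the offsets the ncBAF list, which contains the target Brd9, was called lower in Brd9 knockdown (adjusted p = 0.0348, adjusted p = 0.348 with an estimated correlation as well).

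Histone genes were not called as a list in Brd9, Baf250A or Baf180 knockdown (adjusted p = 0.12, 0.205 and 0.999), although H2bc4 rose 3.75-fold in Baf180 knockdown (log2 fold change 1.91, SE 0.21). HOX genes were not called either (0.336, 0.648 and 0.82). Neither were glycolysis and hypoxia genes (0.0982, 0.188 and 0.388), though Pfkp, a phosphofructokinase, fell 4.29-fold in Baf250A knockdown (−2.10, SE 0.18), or genes of fatty acid synthesis (0.567, 0.474 and 0.665), where Fads2 fell in Baf250A knockdown (−1.41, SE 0.17) and Acacb rose in Baf180 knockdown (3.33, SE 0.47). Oxidative stress and metal genes (0.925, 0.5 and 0.353), epithelial markers (0.985, 0.954 and 0.665) and haematopoietic and endothelial markers (0.473, 0.442 and 0.925) were not called. These values are from camera. The alternative fry called oxidative stress and metal genes higher in Baf180 knockdown (adjusted p = 0.0218). It called histone genes lower in Brd9 and Baf250A knockdown (0.0203 and 0.00496), where 0 and 4 of 20 members were called lower and 0 higher. Fatty acid synthesis genes were called by fry higher in Brd9 and Baf180 knockdown (0.012 and 0.0139) and lower in Baf250A knockdown (0.00811). Of 20 members, 3 were called higher and 1 lower in Brd9, 4 and 4 in Baf180, and 2 and 5 in Baf250A knockdown. The median in Baf250A knockdown was 0.01, so these calls do not show a common shift of the members.

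The test of a GC bias from library preparation was chosen after the trend was seen. In 3 of the 4 groups the 2 replicates differed along GC content with a Spearman rho beyond 0.3 (−0.63 in Brd9, 0.74 in Baf250A and 0.62 in Baf180 libraries), which is in line with a bias that arose in library preparation or sequencing. A change in expression that follows GC content may add to it, and 2 libraries per group do not separate these. The trend is not the whole cause of the calls, since at least 70.1% of each knockdown's calls stood in the same direction with the offsets, Pax7 and Nefl among them. Of the calls against scramble, 131 in Baf250A, 99 in Baf180 and 0 in Brd9 knockdown had the other sign with the offsets.

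For scramble replicate 2, the tests of nuclear RNA and of DNA on the 6 genes that rose most were chosen after the result was seen. This library had counts on 1487 genes silent in all others, against 79 to 132 in each other library. Olfactory and vomeronasal receptor genes silent in all others had 1.24 times the counts per kb of other silent coding genes (95% interval 1.11 to 1.38). Traces of genomic DNA could give such a rate. Mrgpra6, Kcnq1ot1, Grk4 and the other 3 genes had at least 129 times the counts per kb of silent genes, but they were picked for their rise in this library, so whether DNA adds to them stays open. More nuclear RNA may contribute, as the nuclear RNAs Malat1 and Neat1 were 4.06 and 4.60 times as high as in scramble replicate 1. Kcnq1ot1, also nuclear, was 24.0 times as high, but it is among the 6 genes picked for their rise and adds no evidence here.

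For the genes called in the same direction in all 3 knockdowns, the simulation of shared controls was chosen after the result was seen. Chance values of the shared scramble libraries may account for part of the 300 genes, and this stays open, as the simulated unchanged groups had at most 0 shared calls and do not measure it. Without scramble replicate 2 the median fold changes of the 300 genes were at least 0.959 of those in the full fit, though fewer of them were called. The difference of these genes was thus seen against scramble replicate 1 as well. They were called with both scramble libraries, which favours genes on which the 2 agree. The ratio was therefore partly set in advance, and does not measure how far scramble replicate 2 shaped the calls. A difference of the scramble line from unmodified cells could give part or all of the changes common to the 3 knockdowns. The same holds for the lists called in the same direction in all 3. These were extracellular matrix genes, smooth muscle and adipogenic markers and targets of transforming growth factor beta and BMP, called higher, and neural markers, called lower. The design has 1 control line, which leaves this question open. Nefl also differed between the knockdowns, at 50.5 ± 2.58, 11.6 ± 0.179 and 1.98 ± 0.511 CPM in Brd9, Baf250A and Baf180 knockdown. That difference does not involve the scramble line, so it does not decide the question.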
